A study of Mus musculus with 8 samples.

How the data were processed

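RNA was measured by sequencing in 8 libraries of MC3T3-E1 cells, an established line of mouse calvarial pre-osteoblasts. Of these libraries, 4 came from cells grown for 3 days with TABS (the submitters' Trio-Active bone scaffold) and 4 from cells grown for the same time with HA, a hydroxyapatite scaffold doped with magnesium. What makes up TABS is not given in the sources used here. All 8 libraries came from cells grown with a scaffold, with none without. A rise or fall in TABS is therefore relative to HA, and could be a change on HA instead. Per the labels' protocols, RNA was taken up in TRIzol and had an integrity number above 7, and NEBNext Ultra libraries were read on a NovaSeq instrument as paired reads of 150 bases. Nothing in the labels says that the replicates of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

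The deposited table held 1 FPKM value (fragments per kilobase, scaled to the library's fragments) per gene and library, which the authors made before deposit. Per the submitters' processing notes, fastp, STAR and DESeq2 were used, with the mouse build GRCm38. Their versions and roles, the program that made the FPKM values, the annotation release and the strand setting are not given in the sources used here. Because the strand setting is not stated, reads of overlapping and antisense genes cannot be told apart. Among the tested genes named here, exons overlap those of another gene in Piezo1 (Ctu2), Ctsl (Gm47123), Tagln (Gm48529), Fosl1 (Ccdc85b), Aldh1l2 (D10Wsu102e), Selenoo (Tubgcp6), Ctsd (Gm49369), Sephs2 (Gm44729), Mmp19 (Tmem198b), Runx2 (Runx2os1) and Ctsa (Pltp). Shorter overlaps are found in Itga8 (E030013I19Rik), Fgfr2 (Ctbp2), Pappa2 (1600012P17Rik), Spp1 (Gm42793), Tgfb3 (Gm48008), Jun (Junos), Axin2 (Gm11670), Fgfr1 (Gm16159), Col3a1 (Gm47302), Hmga2 (1700006J14Rik), Irf1 (Gm17334), Zfp36 (Gm44710), Fst (Gm47040) and Hmga1 (AI413582). Those of Pth1r (Myl3), F13a1 (Gm30489), Rps20 (Gm24016), Ank (Mir7117), Cebpa (Gm45091), Aspn (Cenpp) and mt-Nd2 (mt-Tw) are shorter than 100 bases. Hmga1 and Hmga1b, and Bglap and its near-identical neighbours, can share reads, so their values are uncertain. Columns were assigned to samples by the library names in the labels, which carry the letter H for TABS and L for HA. These letters do not match the group names, and a swap of the groups would turn every direction. No gene in the data checks which scaffold a library was grown with, so the scaffold labels could not be tested against the values.

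Read totals were not in the table. In single-exon genes with low values, FPKM multiplied by transcript length piled up at multiples of 1 step per library. If that step is 1 fragment, 1 FPKM in a transcript of 1 kilobase stood for 18.2 to 26.1 fragments per library. Only 18.2% to 19.6% of the low values were whole multiples, within 0.02 of a step, so reads were not recovered and no count test was run. No interval that needs read counts is given.

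Of 55335 gene identifiers, 55154 were found in the GENCODE annotation of GRCm38 that gave symbols, coordinates, transcript lengths and GC content, and 27134 were listed at 0 in every library. Genes with an FPKM of at least 1 in at least 4 of the 8 libraries were kept (11280 genes, 10193 of them protein-coding). TABS and HA were compared with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), a pseudocount of 1, with moderated variances that follow the expression level, two-sided, and Benjamini-Hochberg adjusted p under 0.05 as threshold. Fold changes are TABS minus HA on the log2(FPKM + 1) scale, which understates the change of genes with low FPKM. No block was used.

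Gene lists were tested with limma's camera, which compares a list with all other tested genes, at a preset correlation of 0.01 between members. Of 45 lists, 39 had at least 3 tested members, and p was adjusted over these. Camera with an estimated correlation and fry, which tests whether members move one way on balance without comparing them with other genes, were alternatives. Principal component scores and library measures were compared by exact permutation tests over the 70 assignments of 8 libraries to 2 groups of 4, two-sided, with 0.0286 as the smallest possible p.

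The design, the lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule took the 8 genes with the largest fold change in each direction that passed the test with all libraries of one group above all of the other, a mean of at least 2 FPKM in the higher group, and a symbol that is not a predicted gene model. It added up to 3 members of each list by smallest adjusted p, and 10 bone genes (Runx2, Sp7, Alpl, Bglap, Spp1, Ibsp, Col1a1, Tnfsf11, Tnfrsf11b and Vegfa). Postn, Sparc, Omd, Ecm2, Tpm1, Txnrd3, Selenom and Selenoh were named after their values were seen. So were the remaining selenoprotein genes. Some genes taken by the rule or by the lists are not reported here.

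Alternatives covered the pseudocount, the filter on low FPKM, 3 other scalings (TPM, median of ratios and quantiles), the replicate number as a block, other variance settings, library weights, stricter thresholds and leaving out each library in turn. A correction for GC content and transcript length (splines fitted per library to each gene's deviation from its mean over all libraries), its combination with the block, camera on ranks and leaving out mitochondrial genes and their nuclear copies were added after seeing the data. The comparison was tested on simulated data made from the real means and spreads of the 11280 genes. Of genes shifted by 0.25, 0.5 and 1 on the log2 scale, 40.3%, 83.6% and 97.0% were called, with 3 false calls (2% of calls) and 0 calls when nothing was shifted. A list shifted by -0.3 was found and 0 of the other lists were called. The simulated genes varied independently of one another. This therefore does not show how often camera calls lists whose members vary together.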

Results

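Transcript abundance was measured in MC3T3-E1 pre-osteoblasts after 3 days with TABS (n = 4 libraries) or with HA, the magnesium-doped hydroxyapatite scaffold that served as reference (n = 4). Between 11187 and 11357 genes reached 1 FPKM per library. The total of all FPKM values ran from 304893 to 307263 in TABS and from 312629 to 317439 in HA. By the implied depth, 1 FPKM in a transcript of 1 kilobase stood for 18.2 to 24.6 fragments in TABS and 21.0 to 26.1 in HA. No 2 libraries held identical values, and each of the 8 libraries correlated best with a library of its own group (Pearson r across genes 0.987 to 0.992 within groups and 0.985 to 0.990 between them). The first principal component held 25.9% of the variance and parted TABS from HA (exact permutation p = 0.0286, two-sided, the smallest that 70 assignments allow). Mitochondrial genes took 11.5% ± 0.93 of the summed FPKM in TABS and 13.1% ± 1.22 in HA (SD, n = 4, exact permutation p = 0.143, 0.314 adjusted over 4 library measures). The share of the 10 highest genes, that of ribosomal protein genes and the number of genes at 1 FPKM did not pass the test either (adjusted exact permutation p = 0.314 for each). Within HA the 3 shares ran in order from HA 1 to HA 4. The mitochondrial share rose from 12.1% to 14.5% and that of the 10 highest genes from 13.0% to 15.7%, while the ribosomal protein share fell from 7.3% to 6.5%. Scores on the second principal component (17.7% of the variance) fell over these libraries from 15.4 to -11.0, against -6.34 to 0.28 in TABS.

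The comparison asked how the transcriptome of these cells on TABS differed from that on HA. Ibsp, which encodes the mineral-binding matrix protein bone sialoprotein, fell from 50.3 ± 3.58 FPKM in HA to 14.5 ± 1.32 in TABS (SD, n = 4, log2 fold change -1.73 ± 0.07 SE, limma adjusted p = 1.51e-05). Selenow, a small selenoprotein gene, fell from 318 ± 40.6 to 112 ± 9.17 FPKM (-1.50 ± 0.09, adjusted p = 0.000172). Angptl7, a secreted angiopoietin-like protein gene, rose from 2.80 ± 0.39 to 7.66 ± 1.43 FPKM (1.18 ± 0.12, adjusted p = 0.00103). Dmp1, a phosphoprotein gene of osteocytes and mineralising matrix, rose from 17.6 ± 2.36 to 31.6 ± 1.93 FPKM (0.82 ± 0.09, adjusted p = 0.000999). In GRCm38, Ibsp (ENSMUSG00000029306) lies on chromosome 5 from 104299171 to 104311469 and Dmp1 (ENSMUSG00000029307) on the same chromosome from 104202613 to 104214102. Selenow (ENSMUSG00000041571) lies on chromosome 7 from 15917208 to 15922402, and Angptl7 (ENSMUSG00000028989) on chromosome 4 from 148495183 to 148500460. All 4 are annotated as protein-coding.

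In all, 833 of 11280 genes differed (limma, adjusted p under 0.05), 506 higher and 327 lower in TABS, with a median absolute log2 fold change of 0.27. On the log2(FPKM + 1) scale, changes of at least 2-fold were seen in 9 genes, 2 of them higher and 7 lower. This scale shrinks changes at low FPKM. Called genes such as Alpl (1.36 FPKM in HA and 0.46 in TABS) and Pth1r (2.06 and 0.92) were therefore not counted. All 4 libraries of one group lay above all 4 of the other in 2030 genes, or 18.0%, against 2.86% by chance. The balance of directions depended on scaling: after rescaling to TPM, 915 genes were higher and 239 lower (79.3% higher, against 60.7% with FPKM as deposited). With median-of-ratios scaling it was 445 and 373 (54.4% higher), and after the GC and length correction, chosen after seeing the data, 492 and 455 (52.0%). With 1 library left out the count fell to 446, 480, 415 and 488 without TABS 1, 2, 3 and 4, and to 518 and 506 without HA 2 and HA 3. With no filter on low FPKM (542 genes) the calls on Axin2, Col1a1, Col2a1, Etv5, Gpx1, Hmga1, Hmmr, Lyz2, mt-Nd2, Myl9, Spp1 and Tpm1 were lost (adjusted p from 0.0515 for Gpx1 to 0.164 for Spp1). With the replicate number as a block (230 genes) those on Axin2, Col1a1, Col2a1, Etv5, Hmmr, Lyz2, mt-Nd2, Myl9, Spp1 and Tpm1 were lost, as were those on Aldh1l2, Axl, C3, Ctsa, Ctsd, Ctsl, Fgfr1, Hyou1, Nqo1, Plin2, Ptges, Rps20, Sema3b, Tagln, Tgfbi and Zfp36 (from 0.0535 for Tgfbi to 0.163 for Hmmr).

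**Figure D1:**
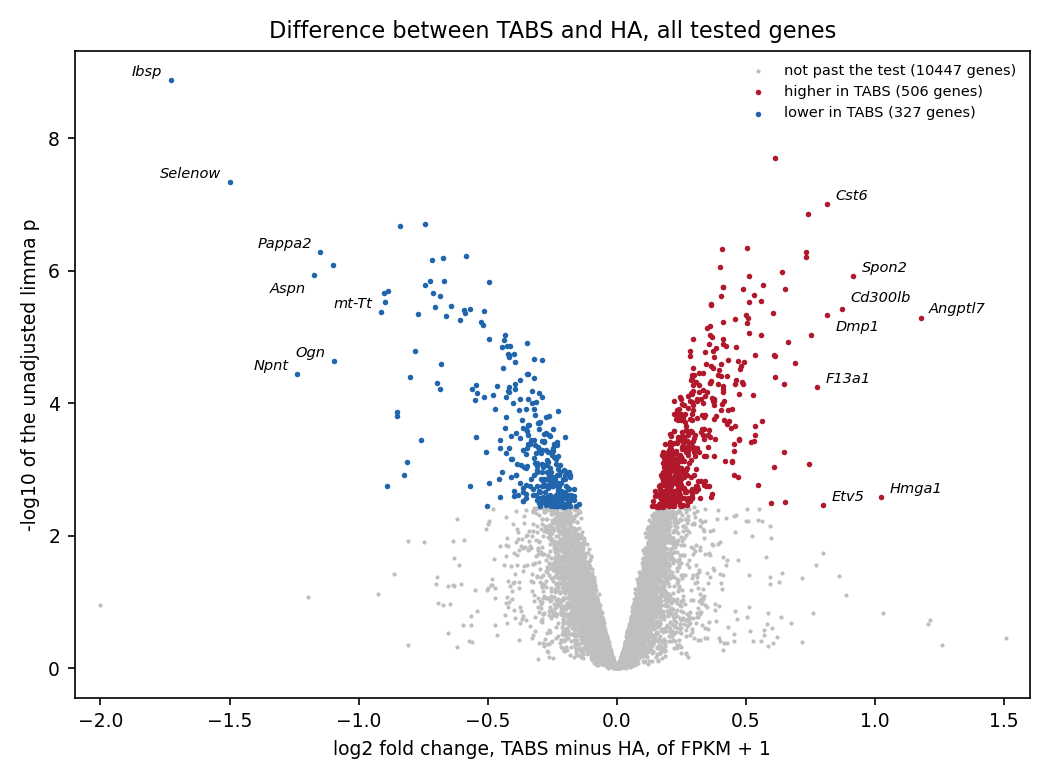
Each point is 1 of the 11280 tested genes, with the log2 fold change of FPKM + 1 (TABS minus HA) on the horizontal axis and -log10 of the unadjusted limma p on the vertical axis. Red and blue points are the 506 higher and 327 lower genes, and genes among those with the largest changes are named, with Ibsp farthest from the rest at -1.73.

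Among the remaining genes with the largest changes, Spon2 (0.92), Cst6 (0.82), Cd300lb (0.87) and F13a1 (0.78) rose. Spon2 encodes a secreted matrix protein, Cst6 a cystatin protease inhibitor, Cd300lb an immunoglobulin-family receptor and F13a1 a transglutaminase chain. Hmga1, a chromatin protein gene, stood at 25.8 ± 12.4 FPKM in TABS and 11.4 ± 1.98 in HA (log2 fold change 1.03, adjusted p = 0.0417), with 44.2 FPKM in TABS 1 and 18.8 to 21.0 in the other TABS libraries. The call on Hmga1 was lost without any single library except TABS 1 (adjusted p up to 0.0975), and without TABS 1 its fold change was 0.74 with adjusted p = 0.0132. It was lost in 10 of 23 alternatives, among them robust variances (0.0814). Etv5, an ETS-family transcription factor gene, stood at 9.56 ± 0.34 and 5.31 ± 1.80 FPKM (0.80, adjusted p = 0.0482). Its call was lost in 18 of 23 alternatives, and without any single library except HA 3 (adjusted p up to 0.112). Genes that fell were Npnt, an integrin ligand (-1.24), Aspn and Ogn, small leucine-rich matrix proteoglycans (-1.17 and -1.09), and Pappa2, a protease of IGF-binding proteins (-1.15). The mitochondrial threonine tRNA gene mt-Tt (-0.91) also fell, but it is shorter than the reads, so its FPKM is uncertain.

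Genes of osteoblast differentiation were lower on TABS as a list. Of 22 tested members of this list, 10 fell, 2 rose and 10 did not pass the test (12 lower and 3 higher adjusted over the list alone). The median log2 fold change was -0.28, with camera adjusted p = 5.86e-07 (adjusted p = 0.133 with an estimated correlation). Besides Ibsp and Ogn, the matrix genes Postn (from 362 ± 34.2 to 194 ± 20.5 FPKM, -0.90), Omd (-0.88), Sparc (-0.40) and the collagen gene Col1a1 (from 1171 ± 141 to 889 ± 27.3 FPKM, -0.39 ± 0.08, adjusted p = 0.0269) fell. The call on Col1a1 was lost without any of TABS 1, 2, 3 and 4 or HA 2 (adjusted p up to 0.0743) and with quantile normalization (adjusted p = 0.074). Sp7, the osteoblast transcription factor osterix, fell from 15.6 ± 0.85 to 10.8 ± 0.18 FPKM (-0.49 ± 0.05, adjusted p = 0.00071). Alpl, tissue-nonspecific alkaline phosphatase, fell from 1.36 ± 0.31 to 0.46 ± 0.06 FPKM (-0.68 ± 0.09, adjusted p = 0.00267), and Pth1r, the parathyroid hormone receptor, from 2.06 ± 0.20 to 0.92 ± 0.04 (-0.67). Runx2, the master regulator of the lineage, did not pass the test at 17.3 ± 0.46 FPKM in TABS and 18.4 ± 0.70 in HA (-0.08 ± 0.04, adjusted p = 0.245). All 4 TABS libraries nevertheless lay below all 4 HA libraries for Runx2. Runx2 passed after the GC and length correction (-0.15, adjusted p = 0.0363), but not with that correction and the block (0.101). Bglap, osteocalcin, did not pass the test (1.23 ± 0.23 and 1.64 ± 0.39 FPKM in TABS and HA, -0.24 ± 0.11, adjusted p = 0.233).

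Genes of osteocytes and mineralisation were higher on TABS as a list. Of 8 tested members, 3 rose, 0 fell and 5 did not pass the test (5 and 0 adjusted over the list alone, and 5 higher after rescaling to TPM). Camera gave adjusted p = 0.000902 (adjusted p = 0.133 with an estimated correlation). The 3 were Dmp1, Fam20c, a kinase of secreted phosphoproteins (from 17.1 ± 0.40 to 24.7 ± 1.83 FPKM, 0.51), and Ank, a membrane protein that raises extracellular pyrophosphate, an inhibitor of mineral formation (from 120 ± 9.69 to 182 ± 7.50 FPKM, 0.60). Ank stood in the osteoblast list too, where it rose with Spp1, the gene of osteopontin, a phosphoprotein known to restrain crystal growth. Spp1 rose from 2431 ± 259 to 3305 ± 239 FPKM (0.45 ± 0.09, adjusted p = 0.0207), a call that was lost without TABS 1, TABS 2 or HA 2 (adjusted p up to 0.0633), with no filter on low FPKM (0.164) and with the replicate number as a block (0.103).

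**Figure D2:**
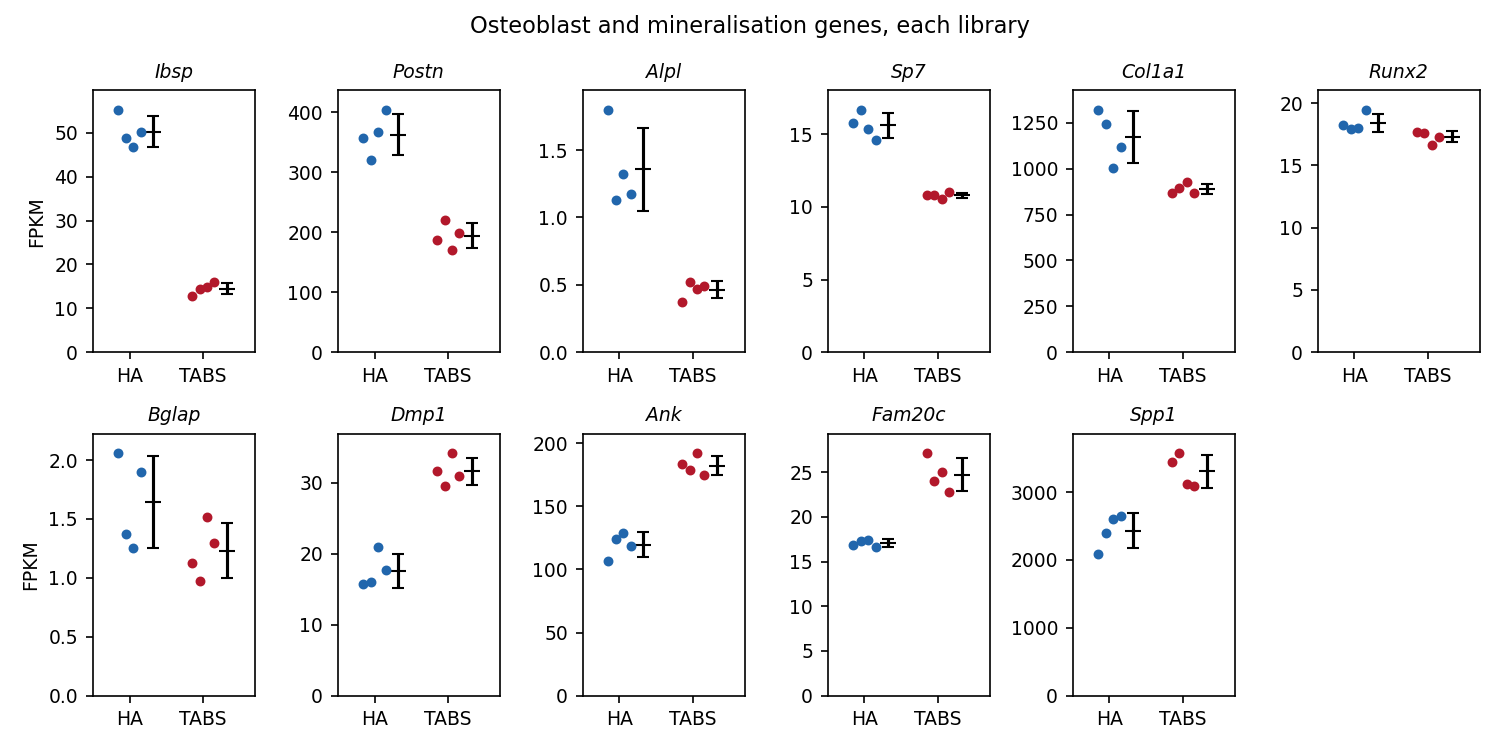
FPKM of 11 bone genes in each library, with HA in blue and TABS in red, and the group mean with its SD in black (n = 4 per group, each vertical axis starting at 0). All TABS libraries lay below all HA libraries for Ibsp, with group means of 14.5 and 50.3, and above them for Dmp1, with means of 31.6 and 17.6, while Runx2 and Bglap did not pass the test. For Runx2, too, all TABS libraries lay below all HA libraries, but by little, with means of 17.3 and 18.4.

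The collagen and matrix assembly list did not pass as a group, with 5 of 31 members lower and 2 higher (9 and 4 adjusted over the list alone, camera adjusted p = 0.101). It did without HA 3 (adjusted p = 0.00629) and after the GC and length correction (0.00584, or 0.00933 with the block). The 5 lower genes became 3 without TABS 1, 3 or 4 or HA 2, and 9 after the correction, and the 2 higher genes became 1 without TABS 1, TABS 2, TABS 3 or HA 3 and with the block. Col3a1 fell from 196 ± 14.4 to 124 ± 9.21 FPKM (-0.66) and Col5a2 by 0.32 on the log2 scale, and the crosslinking enzyme gene Loxl1 rose (0.49). Among matrix proteases and their inhibitors, 4 of 17 rose and 2 fell (7 and 4 adjusted over the list alone, camera adjusted p = 0.396, with 7 higher after rescaling to TPM and 2 and 1 with the block), including Plat (0.33), Mmp19 (0.30) and Adamts1 (-0.43). Of 5 tested markers of contractile myofibroblasts 4 fell and 0 rose (also 4 and 0 adjusted over the list alone, camera adjusted p = 0.00131, adjusted p = 0.378 with an estimated correlation). The smooth-muscle actin gene Acta2 fell from 188 ± 12.0 to 116 ± 10.1 FPKM (-0.70), with Tagln (-0.37), Myl9 (-0.43) and Tpm1 (-0.23). The call on Myl9 was lost without TABS 2 or TABS 3 (adjusted p up to 0.0537). That on Tpm1 was lost without TABS 1, 3 or 4, HA 2 or HA 3 (up to 0.0872), and 2 of the 4 calls were left without TABS 3. Regrouping the 8 libraries gave a p as small for this list in 2 of 35 splits.

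Lysosome and autophagy genes rose as a list. Of 24 tested, 7 rose and 1 fell (12 and 1 adjusted over the list alone), with camera adjusted p = 0.000902 (adjusted p = 0.378 with an estimated correlation). The cathepsin genes Ctsd (from 575 ± 12.8 to 730 ± 46.7 FPKM, 0.34), Ctsl (0.28) and Ctsa (0.27) were among the 7, with the call on Ctsa lost without TABS 1 or TABS 3 (adjusted p up to 0.0521). The 7 became 2 without TABS 1 or TABS 3, 3 without TABS 2 or TABS 4, 4 without HA 2, HA 3 or HA 4, 0 with the block and 12 after rescaling to TPM, while the list passed in each. Of 12 tested genes of neurotrophic factors and axon guidance, 7 rose and 0 fell (7 and 0 adjusted over the list alone, camera adjusted p = 0.0299, adjusted p = 0.414 with an estimated correlation). They included the semaphorin genes Sema7a (0.39) and Sema3b (0.29), and the semaphorin receptor gene Nrp2 (0.31). The 7 became 4 without any 1 library except HA 1 or HA 4, and 3 with the block. The call on this list was lost without TABS 1 (adjusted p = 0.0543) or HA 3 (0.0641), after rescaling to TPM (0.0685), with the block (0.056), with a filter of 5 FPKM (0.422) and with camera on ranks (0.264).

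**Figure D3:**
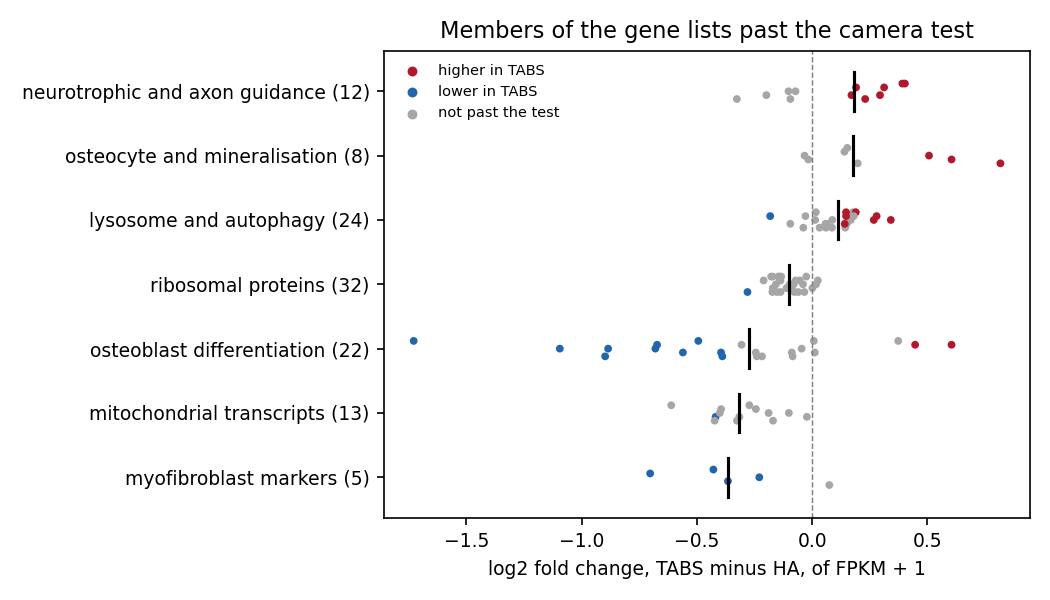
Log2 fold change of FPKM + 1 (TABS minus HA) of each tested member of the 7 lists past the camera test, with the number of members in parentheses and a black line at the median. Red and blue points passed the test per gene, and the osteoblast list spans the widest range, from -1.73 for Ibsp to 0.60 for Ank.

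Transcripts encoded in the mitochondrial genome and ribosomal protein genes were lower as lists, with few calls on single genes. Of 13 mitochondrial genes 1 fell, mt-Nd2 (from 2813 ± 162 to 2108 ± 190 FPKM, -0.42), or 2 adjusted over the list alone. The list had a median of -0.32 and camera adjusted p = 9.8e-05 (adjusted p = 0.533 with an estimated correlation). After the GC and length correction neither the list (adjusted p = 0.367) nor mt-Nd2 (0.0737) passed. Fold changes followed transcript GC content across genes (Spearman 0.35 over 11277 genes, which are not independent replicates). Of 32 ribosomal protein genes 1 fell, Rps20 (-0.28, also 1 adjusted over the list alone), with a median of -0.10 and camera adjusted p = 0.000127 (adjusted p = 0.682 with an estimated correlation). Rps20 did not pass after the GC and length correction (adjusted p = 0.162), nor did the list after quantile normalization (0.0805). Other splits of the 8 libraries gave p-values as small for both lists, the real split being 1 of 5 for mitochondrial and 1 of 10 for ribosomal protein genes among 35. Of 34 nuclear genes of oxidative phosphorylation, 0 changed (also 0 adjusted over the list alone, camera adjusted p = 0.56).

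No list of growth factors and signalling passed camera, and most of them held calls in both directions. After the GC and length correction the Wnt (adjusted p = 0.0402), Notch (0.0321) and osteoclast regulator (0.0416) lists passed. With fry the osteoclast regulator (adjusted p = 0.0214) and BMP and TGF-beta (0.0455) lists passed, both higher on TABS. In the IGF, FGF and PDGF list 3 of 16 rose and 4 fell (6 and 5 adjusted over the list alone, camera adjusted p = 0.906). The 3 became 1 without TABS 1, TABS 2, TABS 3 or HA 3, the 4 became 1 without TABS 3 and 2 without any other library, and the block left 0 and 1. The receptor gene Fgfr2 fell from 19.3 ± 0.95 to 12.6 ± 0.51 FPKM (-0.58) and Fgfr1 rose from 35.4 ± 0.56 to 41.5 ± 0.51 (0.22). Of 23 BMP and TGF-beta genes 4 rose and 2 fell (5 and 2, adjusted over the list alone, camera adjusted p = 0.384), with 1 lower without TABS 3 or TABS 4, and 1 and 1 with the block. Tgfb3 (0.28) and the TGF-beta-induced matrix gene Tgfbi (0.56) rose, and the activin antagonist gene Fst fell (-0.40). Of 17 Wnt genes 1 rose, Wnt5b (0.66), and 1 fell, Axin2 (-0.35, lost without TABS 1, 2 or 3, HA 1, HA 2 or HA 4, adjusted p up to 0.0626), or 1 and 4 adjusted over the list alone (camera adjusted p = 0.384). None of 4 Notch genes passed (0 and 1 adjusted over the list alone, camera adjusted p = 0.443, with 0 or 1 lower with 1 library left out). Of 17 immediate early genes 4 rose and 1 fell (4 and 5 adjusted over the list alone, camera adjusted p = 0.843). The 4 became 2 without TABS 3, TABS 4, HA 1, HA 2 or HA 4. The AP-1 genes Jun (from 37.6 ± 3.24 to 59.6 ± 1.63 FPKM, 0.65) and Fosl1 (0.53) rose and the mRNA decay factor gene Zfp36 fell (-0.33). Of 10 angiogenic factors 2 rose and 1 fell (4 and 2 adjusted over the list alone, camera adjusted p = 0.56, with 1 or 2 higher and 0 or 1 lower with 1 library left out), with Angptl2 higher (0.38). Vegfa did not pass (7.09 ± 0.34 and 7.26 ± 0.54 FPKM, adjusted p = 0.817). Of 8 regulators of osteoclasts 2 rose and 0 fell (3 and 0 adjusted over the list alone, camera adjusted p = 0.166, with 1 or 2 higher with 1 library left out and 1 with the block), including the prostaglandin synthase gene Ptges (0.26). Tnfsf11, the RANKL gene, was listed at 0 in every library. Its decoy receptor gene Tnfrsf11b did not pass (28.6 ± 1.18 and 26.5 ± 2.16 FPKM, 0.10, adjusted p = 0.334) unless GC content and length were corrected (0.17, adjusted p = 0.0452, or 0.137 with the block as well).

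Lists tied to the ions of a mineral scaffold held few calls. None of 12 magnesium transport genes passed the test (also 0 adjusted over the list alone, camera adjusted p = 0.887, with 2 higher after rescaling to TPM), and Slc41a1 came nearest (0.15, adjusted p = 0.0724). Of 13 calcium and phosphate genes 1 rose (also 1 adjusted over the list alone, camera adjusted p = 0.906), the mechanically gated channel gene Piezo1 (from 30.0 ± 1.39 to 40.3 ± 1.77 FPKM, 0.41). Among 13 metal response genes 1 rose (1 and 1 lower adjusted over the list alone, camera adjusted p = 0.725, with 0 or 1 lower with 1 library left out) and among 15 genes of iron handling and ferroptosis 2 rose (3 adjusted over the list alone, camera adjusted p = 0.687). These were the zinc and iron importer gene Slc39a14, shared by both lists (0.34), and the ferrireductase gene Steap3 (from 20.4 ± 0.82 to 34.8 ± 2.12 FPKM, 0.74). Of 23 integrin and adhesion genes 2 rose and 2 fell (2 and 2 adjusted over the list alone, camera adjusted p = 0.443, with 1 or 2 higher and 1 lower with 1 library left out), with Itgb5 higher (0.36) and Itga8 lower (-0.33). Of 13 YAP and mechanical response genes 2 rose and 1 fell (3 and 2 adjusted over the list alone, camera adjusted p = 0.443, with 0 higher with the block), with the receptor gene Axl higher (0.23) and the matricellular gene Ccn1 lower (-0.50). With fry the iron list (adjusted p = 0.00206) and the integrin and adhesion list (0.00445) passed, both higher on TABS.

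Growth and stress lists held few calls, and none passed camera in the planned fit. The ATF4 list passed with library weights (adjusted p = 0.0466), with mitochondrial genes left out (0.0471), without TABS 3, TABS 4, HA 3 or HA 4 (from 0.0112 to 0.0343) and after the GC and length correction (0.00342). The inflammatory and senescence lists passed without HA 3 (0.0368 for each) and after the correction (0.0297 and 0.0416), and the hypoxia and glycolysis list passed without HA 1 (0.000692). With no filter on low FPKM the ATF4 (0.0128), inflammatory and fatty acid synthesis lists (0.0496 for each) passed. Fry called the senescence (adjusted p = 0.000429) and inflammatory (0.0142) lists, both higher on TABS. Of 24 proliferation genes 0 rose and 1 fell (0 adjusted over the list alone, camera adjusted p = 0.56), Hmmr (-0.20, adjusted p = 0.048, lost in 15 of 22 alternatives, among them without any 1 library at 0.051 to 0.121). Of 29 DNA replication genes 1 rose and 1 fell (2 and 2 adjusted over the list alone, camera adjusted p = 0.504), with 0 to 2 higher and 0 or 1 lower with 1 library left out. The p53 target list had 1 lower gene of 18 (1 adjusted over the list alone, camera adjusted p = 0.949), and none without any 1 library except HA 1. Of 5 senescence and cell cycle inhibitor genes 1 rose (2 adjusted over the list alone, camera adjusted p = 0.0954), the chromatin gene Hmga2 (from 20.3 ± 1.61 to 29.1 ± 0.44 FPKM, 0.50). In the unfolded protein list 2 of 20 rose (2 adjusted over the list alone, camera adjusted p = 0.504, with 1 or 2 with 1 library left out and 0 with the block), including Hyou1 (0.24). In the ATF4 list 2 of 23 fell (3 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.0566, with 1 or 2 lower with 1 library left out, 0 with the block and 5 after the correction), including Aldh1l2 (-0.27). In the heat shock list 1 of 15 rose and 1 fell (1 and 3 adjusted over the list alone, camera adjusted p = 0.938), with 0 higher and 0 or 1 lower with 1 library left out. Of 24 NRF2 and antioxidant genes 2 rose and 1 fell (4 and 2 adjusted over the list alone, camera adjusted p = 0.357, with 2 to 4 higher with 1 library left out and 0 with the block), with Nqo1 higher (0.26) and the selenoprotein gene Gpx1 lower (-0.36). Among 16 NF-kB and inflammatory genes 2 rose (3 adjusted over the list alone, camera adjusted p = 0.101), C3 (0.26) and Irf1 (0.53). None of 20 interferon response genes and of 29 genes of hypoxia and glycolysis passed (also 0 adjusted over each list alone, camera adjusted p = 0.828 and 0.357), though up to 1 and 3 rose with 1 library left out. Lipid synthesis had 1 higher gene each in the cholesterol list of 22 (Dhcr7, 0.29) and the fatty acid list of 13 (Fasn, 0.27), both also 1 adjusted over the list alone (camera adjusted p = 0.887 and 0.166). Of 12 genes of fatty acid oxidation 1 rose, Plin2 (0.24), and 2 fell (1 and 2 adjusted over the list alone, camera adjusted p = 0.949), with 1 or 2 lower with 1 library left out. In 7 lists (IGF, FGF and PDGF, calcium and phosphate, iron, p53, heat shock, immediate early, fatty acid oxidation) the median, mean and camera direction differed in sign.

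Most markers of other cell types were too low to be tested, but Ctsk, Sox9, Lyz2 and Col11a1 were not. None of 8 endothelial, 7 skeletal muscle and 6 epithelial markers could be tested, the highest group mean being 0.46 FPKM for Ckm in HA. Of 9 macrophage markers 1 was tested (1 lower adjusted over the list alone), Lyz2, at 13.5 ± 2.16 FPKM in TABS and 18.7 ± 1.10 in HA (-0.46, adjusted p = 0.0293, lost without TABS 2 or 3 or any 1 HA library, up to 0.0701), while the other 8 were not tested, the highest being Fcer1g at 0.39 FPKM in TABS and 0.61 in HA. Of 7 osteoclast markers Ctsk (114 and 114 FPKM) and Mmp9 were tested and 0 passed, and of 8 adipocyte markers Fabp4 and Cebpa were tested and 0 passed (0 for both adjusted over the list alone). Of 3 tested chondrocyte markers 1 rose, Col2a1 (from 4.32 ± 0.52 to 5.49 ± 0.21 FPKM, 0.29, adjusted p = 0.0393, lost without any 1 library except HA 2, up to 0.102), also 1 adjusted over the list alone (camera adjusted p = 0.61). Sox9 (36.5 and 34.8 FPKM in TABS and HA) and Col11a1 (10.8 and 11.7) did not pass. None of 3 tested histone genes passed (0 adjusted over the list alone, camera adjusted p = 0.906).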

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

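A library was singled out when its gap to the nearest of the other 3 libraries of its group took up most of the group's range, at a limit that chance passes in about 1 of 20 groups of 4. Of 218 checks on named genes and library measures, 16 passed it. In TABS 1, Hmga1 stood at 44.2 FPKM (18.8 to 21.0 in the others), Slc39a14 at 9.87 (10.4 to 10.5) and Itgb5 at 190 (182 to 183). TABS 2 had Pth1r at 0.862 FPKM (0.933 to 0.938) and Phgdh at 105 (114 to 116), and TABS 3 had Piezo1 at 42.9 (39.1 to 39.7). In HA 1, Angptl7 stood at 2.23 FPKM (2.94 to 3.07), Nrp2 at 28.9 (32.3 to 32.6) and Selenoh at 27.9 (16.3 to 17.0), and in HA 2, Pappa2 stood at 12.7 (11.5 to 11.6) and Sephs2 at 7.10 (7.84 to 7.99). In HA 3, Etv5 stood at 2.63 FPKM (5.95 to 6.49), Irf1 at 3.81 (5.26 to 5.46), Tpm1 at 52.3 (47.1 to 47.8) and Steap3 at 21.6 (19.9 to 20.1), and in HA 4, Aspn stood at 265 (201 to 209). The gaps of Hmga1, Etv5 and Selenoh are large beside the difference between the groups. Selenoh fell by 0.83 on the log2 scale, and its call was lost without TABS 3, TABS 4 or HA 4 (adjusted p up to 0.0745).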

How the results depend on the processing

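Each of the 833 called genes kept its sign in every setting in which it was tested. Settings that change only the filter, the variance model or the block leave the fold change as it was, so its sign could not change there. The genes were called on these same libraries, so a change of sign was unlikely in the other settings as well. Of 93 named genes past the test 48 kept the call in all settings and 69 whenever 1 library was left out. The count was 542 with no filter on low FPKM (28201 genes tested, 195 lower), 252 at adjusted p under 0.01 and 9 with at least 2-fold changes of FPKM + 1. It was 415 to 718 (247 to 429 higher, 168 to 289 lower) with 1 library left out, where fewer libraries remain. Rescaling to TPM gave 915 higher genes, and turned Vegfa, which did not pass, to 0.0087. The GC and length correction, chosen after seeing the data, called 947 genes, of which 619 were shared. The replicate numbers are shared by the groups, and the labels do not say whether they pair the libraries. Same-numbered deviations correlated at -0.10 to 0.10 and others at -0.16 to 0.18. No pairing was seen in these values, but so few pairs cannot exclude it. With the number as a block 230 genes were called (136 higher, 94 lower, 223 shared), with the block and the GC and length correction 331 (169 higher, 162 lower), and the cause was not tested. In place of 7 lists, 11 passed with no filter, 13 with the GC and length correction with or without the block, 11 with fry, 6 to 10 with 1 library left out and 0 (4 at an unadjusted p under 0.05) with an estimated correlation. There adjusted p was 0.133 for the osteoblast and the mineralisation lists, 0.378 for the lysosome and the myofibroblast lists, 0.414 for the neurotrophic, 0.533 for the mitochondrial and 0.682 for the ribosomal protein list. A higher correlation cannot be why the mineralisation list was lost there, since its estimate was -0.0153, below the preset 0.01. Its unadjusted camera p still went from 9.54e-05 to 0.0068. The other lists had estimates above the preset, from 0.0582 for the osteoblast to 0.5221 for the mitochondrial list. The neurotrophic list also missed the threshold with a filter of 5 FPKM (0.422), TPM (0.0685), the block (0.056) and ranks (0.264), and ran from 0.00825 to 0.0641 with 1 library left out (0.0543 without TABS 1, 0.0641 without HA 3). So did the ribosomal protein list with quantile normalization (0.0805) and fry (0.103), the mitochondrial list with the GC and length correction (0.367, or 0.538 with the block) and fry (0.0679), and the myofibroblast list with ranks (0.0656). The causes were not tested. Read depth is implied and not known, so no limit of detection is given.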

Other observations

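Neighbouring bone matrix genes moved together in one cluster and apart in another, a comparison chosen after their values were seen. On chromosome 13, the small leucine-rich proteoglycan genes Aspn, Omd and Ogn and their relative Ecm2 lie near one another between 49504810 and 49624501. All 4 fell, by 1.17, 0.88, 1.09 and 0.41 on the log2 scale (from 219 to 96.4, 17.7 to 9.15, 292 to 136 and 1.93 to 1.20 FPKM), though the call on Ecm2 was lost with the replicate number as a block and the GC and length correction together (-0.31, adjusted p = 0.0937). With that correction alone all 4 calls were kept, but each fall was smaller (-1.01, -0.73, -0.94 and -0.31). On chromosome 5, Dmp1 and Ibsp, which encode mineral-binding phosphoproteins of one family, lie 85068 bases apart on the same strand. Dmp1 rose by 0.82 where Ibsp fell by 1.73, and Spp1, farther along, rose by 0.45. Mepe and Dspp of the same cluster lay below 1 FPKM (means of 0.15 and 0.35 for Mepe in TABS and HA).

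Of 24 selenoprotein genes 18 were tested, 5 fell and 2 rose. The genes that fell were Selenow (-1.50), Selenoh (-0.83), Selenom (-0.59, from 152 to 101 FPKM), Gpx1 (-0.36, from 194 to 150 FPKM) and Txnrd3 (-0.26). The call on Txnrd3 was lost without any single library except TABS 2 or HA 4 (adjusted p up to 0.0841), with no filter on low FPKM (0.0756) and with the replicate number as a block (0.0864), that on Selenoh with no filter (0.0913), and that on Selenoo with the block (0.0589). Sephs2, which encodes the enzyme that makes the selenium donor, rose from 7.71 to 10.6 FPKM (0.41), and Selenoo rose too (0.28). Gpx4 did not pass the test (177 in TABS and 161 FPKM in HA, adjusted p = 0.27).

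Of the tests below, those for a misplaced library and for nuclear copies of mitochondrial genes and the comparison among selenoprotein genes were chosen only after the result was seen. The GC and length correction and the group of 4 selenoprotein genes were also chosen after seeing the data, so no test that uses them was planned. Only 1 of the 35 splits of the 8 libraries, the real one, gave as many changed genes (833, against at most 5 in the others). That share is the lowest this test can give. It argues against a chance division of these libraries. A chance difference between cultures cannot be excluded in this way, since the libraries of a group may not be separate cultures. For the count of lists past camera chance cannot be excluded, since 9 of 35 splits gave as many as the real 7, with up to 9 in others. For single lists, the real split alone (1 of 35) gave a camera p as small for the osteoblast list (1.5e-08, next 1.03e-06), the mineralisation list (9.54e-05, next 0.00124), the lysosome list (0.000116, next 0.000751) and, narrowly, the neurotrophic list (0.00536, next 0.00555). They were among the 7 of 39 lists picked for a small p in the real split, so this does not exclude chance for them. Splits with a p as small numbered 10 of 35 for the ribosomal protein list (real 9.75e-06, lowest other 1.09e-14), 5 for the mitochondrial list (5.03e-06, 3.28e-09) and 2 for the myofibroblast list (0.000202, 0.000121), so chance cannot be excluded for these.

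Lower osteoblast genes with higher mineralisation genes on TABS could be a trend with GC content and length or a misplaced library. Against the first, for the osteoblast genes alone, the mean difference of the 22 members was -0.35 ± 0.03 (SE) after the GC and length correction and -0.34 before it. The mean of the mineralisation genes was not tested in this way. After the correction their list still passed camera (median log2 fold change 0.18, adjusted p = 0.00405). Against the second, in the mean of all tested mineralisation genes minus that of all tested osteoblast genes the lowest TABS library lay 0.51 above the highest HA library, on a log2 scale where the larger SD within a group was 0.083. Moving any 1 library to the other group left at most 4 changed genes in place of 833, though a swap of the whole groups cannot be seen in this way. A response of the cells to either scaffold is a hypothesis that stays open, together with anything else that differed between the cultures, such as cell number, which was not tested.

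The lower mitochondrial list may follow the trend with GC content, since its mean difference went from -0.30 to -0.10 ± 0.08 (SE, exact permutation p = 0.371) after the GC and length correction, and its call ended because the difference shrank. Reads moving from the mitochondrial genes to their nuclear copies are argued against as the whole cause. The summed FPKM of 6 copies was not higher in TABS (log2 ratio -0.18 ± 0.08 SE, exact permutation p = 0.0857). A smaller shift of reads beside a fall of both cannot be excluded in this way. Deviations from the mean over all libraries correlated with GC content at -0.59 in HA 4 and -0.41 in HA 3, the libraries with the highest mitochondrial shares (14.5% and 13.8%). A lower content of mitochondrial RNA on TABS was not tested in another way.

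The fall of Gpx1, Selenow, Selenoh and Selenom, whose transcripts are known to fall when selenium is scarce, is not accounted for by GC content and length, with a mean difference of -0.82 ± 0.07 (SE) after the correction and -0.82 before. Loss of short transcripts is argued against by 337 protein-coding genes of matched length, whose median log2 fold change was -0.0352. The difference between their mean and that of the other 14 selenoprotein genes (-0.88) decides nothing, since the 4 were grouped after their values were seen and are the lowest of the 18. A lower supply of selenium to the cells on TABS, or a higher one on HA, is a hypothesis formed from these values and left open. Selenium was not measured.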
